A study of Mus musculus with 37 samples.

How the data were processed

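RNA from mouse fibroblast cultures was hybridised to 37 Affymetrix MG_U74Av2 oligonucleotide arrays, each measuring 1 sample in 1 colour. NIH3T3 is an established line of mouse fibroblasts. The labels describe parental NIH3T3 cells, NIH3T3 cells transformed by a constitutively active (Q63L) mutant of RhoA, RhoB or RhoC, and parental and RhoA cells treated with Y27632, an inhibitor of the Rho-associated kinases ROCK1 and ROCK2. Sample groups and replicate numbers were taken from the labels, which gave 8 NIH3T3, 7 RhoA, 6 RhoB, 6 RhoC, 5 treated NIH3T3 and 5 treated RhoA arrays. Per the series' design text, total RNA (4 microgram per labelling) was purified on columns and processed with the array maker's standard protocols, the transformed lines were pools of picked foci, and the untreated arrays carry RNA of independent cultures kept in serum. Nothing says this of the treated arrays, so their p-values measure the spread between arrays, which may be technical.

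The deposited table holds 1 signal intensity per probe set and array on a linear scale. The submitters' processing notes and the series' design text name RMA, whose values are usually on a log2 scale. The deposited intensities were linear, and the mean of each array after removal of 2 percent of the values at each end was 500, so each array had been scaled to a common mean. Which step set this scale is not given in the sources used here. Array medians lay between 146 and 186, and single values between 0.0094 and 61251.5. The number of arrays limits the precision, and a signal minimum of 100 was applied as in the design text.

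Of 12488 probe sets, 66 controls were left out and 12422 were tested. The platform annotation that accompanied the series gave 1 gene symbol for 10833 of them and several for 396, and 1193 were not listed there. Entrez identifiers matched 10817 symbols to the RefSeq gene table, which changed 0 of them. The 8251 genes with a probe set of their own include 2073 with more than 1, and a gene is represented by its probe set of highest mean over all arrays. Probe sets of several genes were not named.

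Values were compared as log2 signal with limma (lmFit and eBayes), without an offset and without further normalization. Comparisons between untreated lines used 1 fit of the 27 untreated arrays in 4 groups, and comparisons with Y27632 used 1 fit of the 25 arrays of NIH3T3 and RhoA cells with and without it. A probe set was called when its Benjamini-Hochberg adjusted p was at most 0.01, its fold change at least 1.5 and its mean signal at least 100 in at least 1 of the groups compared. The fold, p and signal limits are those of the design text, which does not name an adjustment of p. Its classes of probe sets common to 3 or 2 GTPases or unique to 1 were computed as written there, with limma's unadjusted p. The words rose, fell and changed are used of called probe sets only.

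The shift of 34 gene lists was tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison and a limit of 0.05. The medians given beside its p-values are of log2 changes and are not what camera tests. Camera with a correlation estimated from each list, and fry, were alternatives. Lists with fewer than 5 measured genes would not have been tested, and all lists had more. A list score is the mean over a list's genes of the log2 signal centred on all arrays. The lists, the comparisons, the limits and the rule for named genes were fixed before the data were examined.

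The rule for named genes took, in each of the 5 main comparisons, the 8 largest rises and 8 largest falls among called genes in which every array of 1 group lay above every array of the other. It added up to 4 called members with the lowest adjusted p of each list described, the genes of the 3 GTPases, Rock1 and Rock2, and the 10 genes of lowest adjusted p for the interaction. The text names a subset of these genes. No probe set named for Rock2 was found.

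Scan day and chip lot were read from the deposited experiment files and numbered, giving 5 scan days and 7 lots. Scan day 1 held 1 NIH3T3, 4 RhoA and 3 RhoB arrays, day 2 held 1 NIH3T3 and 3 RhoC arrays, and day 3 held 3 arrays of each untreated line. Day 4 held 3 NIH3T3 arrays and day 5 all 10 treated arrays. Untreated lines were therefore also compared with scan day as a block and within days. Treated and untreated arrays share no scan day, so that day 5 could enter only as a random block (duplicateCorrelation), and the effect of Y27632 cannot be told apart from an effect of day 5. Treated RhoA and treated NIH3T3 arrays were scanned on 1 day. Camera takes no random block, so list shifts for Y27632 were recomputed with the untreated arrays of day 3 only.

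The slope of the RhoA effect under Y27632 on the effect without it was fitted through the origin by least squares, with an interval from 1000 bootstrap draws of arrays within groups. Alternatives were quantile normalization, median centring, an offset of 16, other limits, other fits of the spread, blocks for replicate number, scan day and lot, array weights, the other probe sets of a gene, and leaving out each array in turn. The alternatives that leave out sets of arrays or use single days were added after the data were seen.

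The steps were tested on simulated data with the real arrays' means and spread over 12422 probe sets. Simulated changes were placed only in probe sets whose mean signal lay well above the minimum of 100. The simulated noise was independent between arrays, without effects of scan day or culture. The shares recovered therefore hold for such probe sets and such noise, and not for all 12422. For RhoA against NIH3T3, 41.8% of probe sets changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold were recovered. For Y27632 in RhoA cells these shares were 28.4%, 77.6% and 98.5%, and for the interaction 10.4%, 61.2% and 93.9%. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.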

Results

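Transcript levels were measured in parental NIH3T3 mouse fibroblasts and in NIH3T3 cells transformed by constitutively active RhoA, RhoB or RhoC, members of the Rho subfamily of small GTPases. Parental and RhoA-transformed cells were also measured after 24 h with 10 µM Y27632, an inhibitor of the Rho-associated kinases. The 37 arrays comprised 8 of NIH3T3, 7 of RhoA, 6 of RhoB, 6 of RhoC, 5 of treated NIH3T3 and 5 of treated RhoA cells. Each array had been scaled to a trimmed mean signal of 500, and their medians lay between 146 and 186. The highest correlation between any 2 arrays was 0.983, and 0 pairs held identical values. Each transformed line was 1 pool of picked foci, so the replicates of a line are cultures of that pool.

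Rhob was higher in the RhoB line, by 0.65 ± 0.15 (log2 ± SE, adjusted p = 0.00208), from 2023 ± 480 (SD, n = 8) to 3151 ± 637 (n = 6). Its call was lost without NIH3T3 replicate 2 (0.57), without RhoB replicate 4 (0.57), without NIH3T3 replicates 1 to 4 (0.49) and on scan day 3 alone (0.96). The difference on scan day 1, with 1 NIH3T3 array, was 0.34. Rhob was not called in RhoC (0.48 ± 0.15, adjusted p = 0.0244), though it was with scan day as a block (0.75, against 0.76 in RhoB), and no direct test between the lines called it (RhoB minus RhoC 0.18 ± 0.16, adjusted p = 0.854). Rhoa in the RhoA line differed from NIH3T3 by -0.23 ± 0.10 (adjusted p = 0.0963), and Rhoc in the RhoC line by 0.29 ± 0.10 (adjusted p = 0.0358), and neither was called. Rhoc was called between RhoA and RhoC (RhoA minus RhoC -0.62 ± 0.10, adjusted p = 0.00391), though not with scan day as a block (-0.50, adjusted p = 0.063). That call was also lost on day 3 alone (-0.46) and without RhoA replicates 1 to 4 (-0.46). In RhoA against NIH3T3 Rhoc was not called over all days (-0.33 ± 0.09) or on day 3 alone (0.01). On scan day 1, which held 1 NIH3T3 array, the RhoA minus NIH3T3 difference was -0.74. No call was made for the kinase gene Rock1 in any line (0.06, -0.07 and 0.20 in RhoA, RhoB and RhoC), though another of its probe sets was called in RhoA (0.59). Whether these probe sets detect the transfected GTPases is not given in the sources used here, so that they do not check the labels.

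The comparison of RhoA with NIH3T3 asks which transcripts differ in cells transformed by active RhoA. Msln, which encodes the cell-surface glycoprotein mesothelin, rose most, by 5.67 ± 0.29 (log2 ± SE), from 68.1 ± 41.8 (SD, n = 8) to 2838 ± 237 (n = 7). The chemokine genes Cxcl5, Cxcl1 and Ccl2 rose by 4.77 ± 0.24, 4.42 ± 0.21 and 4.31 ± 0.24, while the list of 29 cytokine and chemokine genes, with 4 up and 4 down (4 and 4 adjusted over the list alone), did not pass (median 0.36, adjusted p = 0.158). Further rises were seen for Ptgs2, the inducible cyclooxygenase (4.09 ± 0.44), Ngef, an exchange factor for Rho GTPases (3.51 ± 0.17), the growth factor gene Ereg (3.50 ± 0.37) and the skeletal actin gene Acta1 (3.25 ± 0.41). The largest falls included genes of matrix and secreted proteins. The change was -4.64 ± 0.25 for Smoc2 and -4.41 ± 0.20 for Ogn, which went from 3542 ± 1194 to 157 ± 19.6. The growth factor gene Ptn (-4.04 ± 0.25), Sparcl1 (-3.52 ± 0.34) and the basement membrane gene Nid2 (-3.37 ± 0.22) fell too. The cysteine dioxygenase gene Cdo1 (-3.87 ± 0.19), the aldehyde dehydrogenase gene Aldh1a1 (-3.53 ± 0.30) and the angiotensin receptor gene Agtr2 (-3.53 ± 0.40) fell as well. Adjusted p ranged from 1.7e-14 for Ogn to 7.1e-07 for Acta1. Every RhoA array lay on the same side of every NIH3T3 array for each of these genes, which the rule for naming them required. A second probe set of Ereg gave -0.02 and one of Aldh1a1 0.18.

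Genes of cell division rose together in the RhoA line. Of 31 measured G2 and M phase genes, 28 rose and 0 fell (29 adjusted over the list alone). Their median was 1.40 (adjusted p = 7.3e-14, and adjusted p = 0.213 with an estimated correlation). They included the mitotic kinase genes Cdk1 (1.50 ± 0.18) and Aurka (1.93 ± 0.28) and the spindle midzone gene Prc1 (2.06 ± 0.28). Of 32 G1 and S phase genes 21 rose (22 adjusted over the list alone), among them the nucleotide reductase gene Rrm2 (2.49 ± 0.29) and the replication licensing gene Mcm2 (1.49 ± 0.17). The median was 1.10 (adjusted p = 1.4e-10, and adjusted p = 0.154 with an estimated correlation). Of 33 Myc target genes 18 rose (18 adjusted over the list alone), including Odc1 of polyamine synthesis (1.06 ± 0.09) and Shmt1 of one-carbon metabolism (1.25 ± 0.12). Their median was 0.67 (adjusted p = 5.3e-12, and adjusted p = 0.0797 with an estimated correlation). The NIH3T3 arrays differed among themselves in these genes. Their G2 and M phase scores (mean log2 signal, centred on all arrays) were -1.66, -1.61, -1.50, -1.58, 0.14, 0.04, -0.50 and -0.51 in replicates 1 to 8, against 0.44 ± 0.14 (SD, n = 7) in RhoA, 0.26 ± 0.03 (n = 6) in RhoB and 0.17 ± 0.06 (n = 6) in RhoC. Without NIH3T3 replicates 1 to 4 the medians of the G2 and M phase, G1 and S phase and Myc lists were 0.63, 0.63 and 0.52.

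Serum immediate-early genes were higher in RhoA, with 11 of 25 called up and 1 down (12 and 1 adjusted over the list alone). Nr4a1 rose by 2.72 ± 0.28, Ier3 by 2.13 ± 0.20, the phosphatase gene Dusp1 by 1.64 ± 0.14 and Jun by 1.41 ± 0.15. The median was 0.74 (adjusted p = 5.4e-06, and adjusted p = 0.213 with an estimated correlation), and 0.27 without NIH3T3 replicates 1 to 4, whose scores for this list were also the lowest of their group. Of 14 YAP and TEAD target genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with Ccn2 at 2.57 ± 0.30 and Ankrd1 at 1.28 ± 0.12. Their median was 0.28 (adjusted p = 0.00953, and adjusted p = 0.120 with an estimated correlation), and it did not pass on scan day 3 alone (0.13, adjusted p = 0.224). The SRF and MRTF target genes of the actin cytoskeleton had a median of 0.03 (adjusted p = 0.452), with 5 of 23 called up and 1 down (5 and 1 adjusted over the list alone). Fhl1 (3.04 ± 0.30) and Tagln2 (0.99 ± 0.10) were among those that rose. Of 20 cyclin-dependent kinase inhibitor and p53 target genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Cdkn1a, the p21 inhibitor, at 1.25 ± 0.16. The list median was 0.43 (adjusted p = 0.0219, and adjusted p = 0.126 with an estimated correlation), and without NIH3T3 replicates 1 to 4 its adjusted p was 0.0681.

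Matrix genes were lower in RhoA. Of 25 collagen genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with Col6a2 at -2.06 ± 0.11, Col6a1 at -1.45 ± 0.10 and Col3a1 at -1.36 ± 0.11. The median was -0.32 (adjusted p = 0.00257, and adjusted p = 0.134 with an estimated correlation). Of 33 other matrix glycoprotein and proteoglycan genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.44 (adjusted p = 9.3e-05, and adjusted p = 0.0797 with an estimated correlation). Matn2 fell by 2.54 ± 0.14, while Tnc, which encodes tenascin C, rose by 2.45 ± 0.10, from 383 ± 47.1 to 2094 ± 291. Timp3, an inhibitor of metalloproteinases, fell by 3.17 ± 0.16, and Plaur, the receptor of urokinase, rose by 2.26 ± 0.17. Their list of 28 matrix proteases and inhibitors went both ways, with 3 up and 5 down and a median of -0.27 (adjusted p = 0.231). Cholesterol and fatty acid synthesis genes fell in 7 of 21 cases and rose in 0 (7 adjusted over the list alone), including Dhcr7 (-1.52 ± 0.14). The median was -0.37 (adjusted p = 0.000132, and adjusted p = 0.106 with an estimated correlation). Fibroblast and mesenchymal markers had 11 of 23 down and 2 up (11 and 2 adjusted over the list alone). The median was -0.51 (adjusted p = 0.00643, and adjusted p = 0.0797 with an estimated correlation). The receptor gene Pdgfrb fell by 2.23 ± 0.18 and Cd44 rose by 1.97 ± 0.15.

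**Figure D1:**
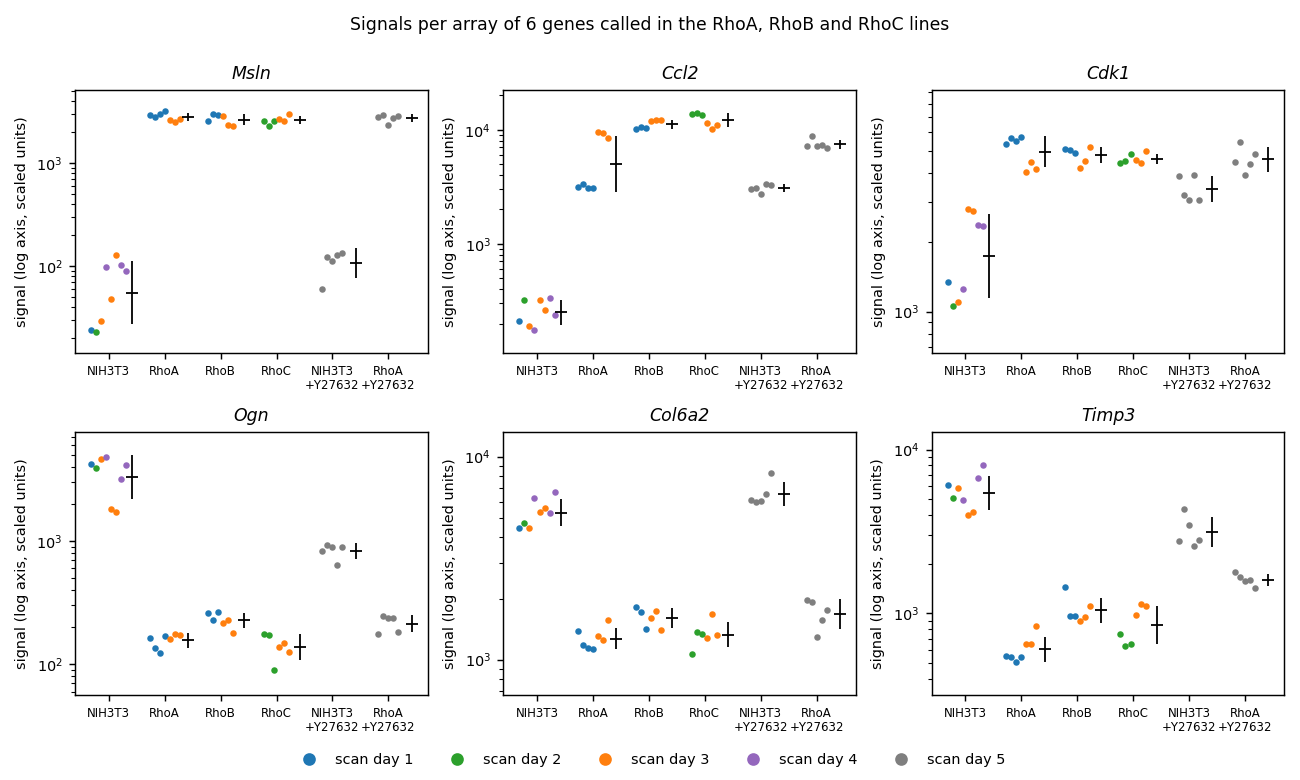
Signal per array (log axis, scaled units) of Msln, Ccl2, Cdk1, Ogn, Col6a2 and Timp3 in the 6 groups, coloured by scan day, with the mean and SD of the log2 signals as a bar beside each group. Msln lay at 2838 ± 237 in RhoA and 68.1 ± 41.8 in NIH3T3 (mean ± SD), and Cdk1 differed among the NIH3T3 arrays.

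In all, limma called 1706 of 12422 probe sets between RhoA and NIH3T3, 872 higher and 834 lower, which is 673 genes higher and 673 lower. With scan day as a block 1538 were called, 1401 of them shared, and within scan day 3 (3 arrays per line) 347, with 1702 of the 1706 in the same direction. The 1706 were called on all days, day 3 included, so the selection favours this agreement in direction. Without NIH3T3 replicates 1 to 4 the count was 1164, of which 1093 were shared. Under the scan day block the 43 called genes named for RhoA kept their calls, at 0.837 to 1.08 times their log2 change. On day 3 alone 28 kept them, at 0.482 to 1.20 times. The calls lost there were those of Ptgs2 (2.81), Ereg (2.82), Acta1 (1.75), Aldh1a1 (-2.33), Cdk1 (1.05), Prc1 (1.54), Aurka (1.16), Rrm2 (1.66), Mcm2 (1.14), Shmt1 (0.94), Nr4a1 (2.34), Dusp1 (1.15), Jun (1.45), Ccn2 (1.24) and Cdkn1a (1.27). List medians with the block and on day 3 alone were 1.41 and 0.75 for G2 and M phase, 1.12 and 0.74 for G1 and S phase, 0.68 and 0.48 for Myc targets, 0.64 and 0.34 for immediate-early genes, -0.44 and -0.49 for collagens, -0.48 and -0.31 for other matrix genes, -0.41 and -0.28 for cholesterol and fatty acid synthesis, and -0.61 and -0.60 for fibroblast markers. Scan day 1 held 1 NIH3T3 array, so only effect sizes are given for it. The 43 genes lay there at 0.746 to 1.51 times their log2 change, in the same direction. The list medians were there, in the same order, 2.36, 1.71, 0.92, 1.14, -0.16 (collagens), -0.74, -0.59 and -0.27. The G2 and M phase medians of single days lean on low NIH3T3 arrays. On day 3 the NIH3T3 scores for this list were -1.50 (replicate 3), 0.14 and 0.04, against 0.29, 0.28 and 0.31 in RhoA. On day 1 the NIH3T3 score was -1.66.

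In the RhoB line 4 of 29 cytokine and chemokine genes rose and 4 fell (5 and 4 adjusted over the list alone), and the list did not pass (median -0.05, adjusted p = 0.356). Cxcl5 rose by 6.04 ± 0.25 (log2 ± SE), from 105 ± 22.3 (SD, n = 8) to 6875 ± 1426 (n = 6), Ccl2 by 5.49 ± 0.25, Cxcl1 by 4.88 ± 0.22 and Ccl7 by 4.71 ± 0.26. Msln rose by 5.58 ± 0.30, Saa3, which encodes a serum amyloid protein, by 5.47 ± 0.56, Ngef by 4.26 ± 0.18 and the water channel gene Aqp1 by 4.19 ± 0.55. Cd24a, a gene of a surface glycoprotein, fell by 4.30 ± 0.14, from 7454 ± 1032 to 383 ± 81.3. Ptn (-4.51 ± 0.26), Smoc2 (-4.48 ± 0.27), Nid2 (-3.99 ± 0.23), Ogn (-3.86 ± 0.21), the secreted Wnt antagonist gene Sfrp2 (-3.31 ± 0.18), the pentraxin gene Ptx3 (-3.29 ± 0.22) and Cdo1 (-3.05 ± 0.20) fell as well. Adjusted p for these genes ranged from 2.0e-17 for Cd24a to 2.1e-06 for Aqp1.

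Of the G2 and M phase genes 26 of 31 rose in RhoB (28 adjusted over the list alone), with a median of 1.19 (adjusted p = 2.1e-14, and adjusted p = 0.235 with an estimated correlation). Of the G1 and S phase genes 21 of 32 rose (22 adjusted over the list alone), with a median of 1.07 (adjusted p = 1.8e-12, and adjusted p = 0.111 with an estimated correlation). Cdk1 rose by 1.46 ± 0.19, Prc1 by 1.85 ± 0.29 and Mcm3 by 1.75 ± 0.23. Without NIH3T3 replicates 1 to 4 the list medians were 0.46 and 0.52. Myc target genes rose in 12 of 33 cases (14 adjusted over the list alone), with a median of 0.47 (adjusted p = 3.8e-12). Immediate-early genes rose in 9 of 25 cases (10 adjusted over the list alone), with Ier3 at 2.34 ± 0.21 and Fosl1 at 1.85 ± 0.22. Their median was 0.51 (adjusted p = 2.1e-05, and adjusted p = 0.275 with an estimated correlation), and 0.18 without NIH3T3 replicates 1 to 4. Of 20 cyclin-dependent kinase inhibitor and p53 target genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.00261). Cdkn1a rose by 1.70 ± 0.17 and Mdm2 by 1.26 ± 0.13. Heat shock and chaperone genes (5 of 19 up, 5 adjusted over the list alone, median 0.45, adjusted p = 0.000309) and glycolysis and hypoxia genes (8 of 25 up and 2 down, 8 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.000243) were also higher.

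Collagens fell in 11 of 25 cases in RhoB and rose in 1 (11 and 1 adjusted over the list alone), with a median of -0.64 (adjusted p = 3.9e-07). Col6a2 (-1.72 ± 0.11) and Col6a3 (-1.54 ± 0.11) were among them. Other matrix genes fell in 13 of 33 cases (14 adjusted over the list alone, median -0.50, adjusted p = 9.3e-07) and fibroblast markers in 12 of 23, with 1 up (12 and 1 adjusted over the list alone, median -0.62, adjusted p = 0.000309). Timp3 (-2.39 ± 0.17) and the mesenchymal homeobox gene Prrx2 (-1.93 ± 0.13) fell, while Cd44 rose by 1.74 ± 0.16, with another of its probe sets at -0.14. Of 21 cholesterol and fatty acid synthesis genes 9 fell (9 adjusted over the list alone), among them Hmgcs1 (-1.03 ± 0.09) and Dhcr7 (-1.71 ± 0.15), with a median of -0.54 (adjusted p = 1.5e-09). With an estimated correlation these 4 lists kept their calls, at adjusted p = 0.0130, 0.0175, 0.0130 and 0.0100, as did the Myc (0.0448), p53 (0.0386), heat shock (0.0051) and glycolysis (0.0051) lists.

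Limma called 1269 probe sets between RhoB and NIH3T3, 661 higher and 608 lower (519 and 477 genes), of which 52.1% were higher, against 66.7% after median centring. With scan day as a block 1125 were called (1003 shared), and without NIH3T3 replicates 1 to 4 812. Within day 3 the count was 428 (389 shared). All 31 called genes named for RhoB kept their calls with the block, at 0.877 to 1.17 times their log2 change, and 27 did on day 3 alone, at 0.721 to 1.47 times. The calls of Rhob (0.96), Cdk1 (1.18), Prc1 (1.48) and Mcm3 (1.45) were lost there. List medians with the block and on day 3 alone were 1.14 and 0.66 for G2 and M phase, 1.13 and 0.92 for G1 and S phase, 0.53 and 0.47 for Myc targets, 0.47 and 0.11 for immediate-early genes, 0.41 and 0.37 for p53 targets, -0.69 and -0.79 for collagens, -0.49 and -0.56 for other matrix genes, -0.54 and -0.41 for cholesterol and fatty acid synthesis, and -0.61 and -0.75 for fibroblast markers. On day 1, which held 1 NIH3T3 array, they were 2.06, 1.601, 0.63, 0.95, 0.50, -0.32, -0.64, -0.85 and -0.39. The called genes named for RhoB kept their direction there, at 0.514 to 1.52 times their log2 change. For G2 and M phase both days lean on low NIH3T3 arrays (replicate 3 on day 3, score -1.50, and replicate 1 on day 1, score -1.66).

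In RhoC cells Cxcl5 rose by 5.93 ± 0.25 (log2 ± SE), Ccl2 by 5.61 ± 0.25, Saa3 by 5.60 ± 0.56, Msln by 5.56 ± 0.30, Cxcl1 by 5.22 ± 0.22 and Ccl7 by 4.72 ± 0.26. The gene of the peptide hormone cholecystokinin, Cck, rose by 4.62 ± 0.47, from 34.2 ± 25.9 (SD, n = 8) to 696 ± 157 (n = 6), and Aqp1 by 4.46 ± 0.55, with another of its probe sets at -0.48. The cytokine and chemokine list, with 5 of 29 up and 4 down (5 and 4 adjusted over the list alone), did not pass (median 0.35, adjusted p = 0.0597). Ptn fell by 4.94 ± 0.26. Further falls were those of Agtr2 (-4.63 ± 0.42), Ogn (-4.59 ± 0.21), Nid2 (-4.00 ± 0.23), Smoc2 (-3.99 ± 0.27), Trim30a (-3.78 ± 0.53), Sparcl1 (-3.56 ± 0.36) and Sfrp2 (-3.22 ± 0.18). Adjusted p for these genes ranged from 7.9e-15 for Cxcl5 to 5.9e-06 for Trim30a.

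Of 31 G2 and M phase genes 23 rose in RhoC (28 adjusted over the list alone), with a median of 1.13 (adjusted p = 8.2e-13, and adjusted p = 0.226 with an estimated correlation). Of 32 G1 and S phase genes 20 rose (21 adjusted over the list alone), with a median of 0.90 (adjusted p = 1.6e-11, and adjusted p = 0.130 with an estimated correlation). Cdk1 rose by 1.41 ± 0.19, Prc1 by 1.76 ± 0.29 and Rrm2 by 2.25 ± 0.30. Without NIH3T3 replicates 1 to 4 the medians were 0.36 and 0.46. Myc target genes rose in 11 of 33 cases (11 adjusted over the list alone), with a median of 0.48 (adjusted p = 1.0e-09, and adjusted p = 0.112 with an estimated correlation). Immediate-early genes rose in 11 of 25 cases (13 adjusted over the list alone), with Ier3 at 2.61 ± 0.21 and Fosl1 at 1.81 ± 0.22. The median was 0.85 (adjusted p = 3.9e-08, and adjusted p = 0.130 with an estimated correlation), and 0.29 without NIH3T3 replicates 1 to 4. The matricellular gene Ccn1, which is also a YAP target, rose by 1.74 ± 0.27. Of the p53 target list 9 of 20 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.56, adjusted p = 0.00148), with Cdkn1a at 1.74 ± 0.17 and Mdm2 at 1.21 ± 0.13.

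In RhoC cells 10 of 25 collagens fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.47 (adjusted p = 1.8e-06). Col6a2 (-1.99 ± 0.11) and Col3a1 (-1.86 ± 0.12) were among them. Other matrix genes had 14 of 33 down and 2 up (15 and 2 adjusted over the list alone, median -0.44, adjusted p = 1.6e-05), and fibroblast markers 11 of 23 down and 1 up (11 and 1 adjusted over the list alone, median -0.38, adjusted p = 0.000982). Timp3 (-2.68 ± 0.17), Prrx2 (-1.68 ± 0.13) and Dhcr7 (-1.39 ± 0.15) fell, and Cd44 rose by 1.89 ± 0.16. Cholesterol and fatty acid synthesis genes fell in 5 of 21 cases (5 adjusted over the list alone, median -0.41, adjusted p = 1.8e-06). The collagen, other matrix, fibroblast, cholesterol and p53 lists kept their calls with an estimated correlation, at adjusted p = 0.0352, 0.0417, 0.0352, 0.0379 and 0.0379.

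Limma called 1127 probe sets between RhoC and NIH3T3, 601 higher and 526 lower (464 and 429 genes). With scan day as a block 1175 were called (923 shared), within day 3 323 (287 shared), and without NIH3T3 replicates 1 to 4 753. Day 2 held 1 NIH3T3 array, and there 1126 of the 1127 had the same direction. The 1127 were called on all days, day 2 included, so the selection favours this agreement. The 30 called genes named for RhoC kept their calls with the block, at 0.872 to 1.14 times their log2 change, and 25 did on day 3 alone, where Trim30a (-3.37), Cdk1 (1.19), Prc1 (1.46), Rrm2 (1.56) and Ccn1 (1.01) lost theirs. List medians with the block and on day 3 alone were 1.25 and 0.61 for G2 and M phase, 1.06 and 0.69 for G1 and S phase, 0.50 and 0.45 for Myc targets, 0.60 and 0.25 for immediate-early genes, 0.54 and 0.36 for p53 targets, -0.60 and -0.66 for collagens, -0.67 and -0.58 for other matrix genes, -0.34 and -0.18 for cholesterol and fatty acid synthesis, and -0.60 and -0.56 for fibroblast markers. On day 2 they were 1.93, 1.38, 0.63, 1.63, 0.71, -0.56, -0.61, -0.58 and -0.60. For G2 and M phase both days lean on low NIH3T3 arrays (replicate 3 on day 3, score -1.50, and replicate 2 on day 2, score -1.61).

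**Figure D2:**
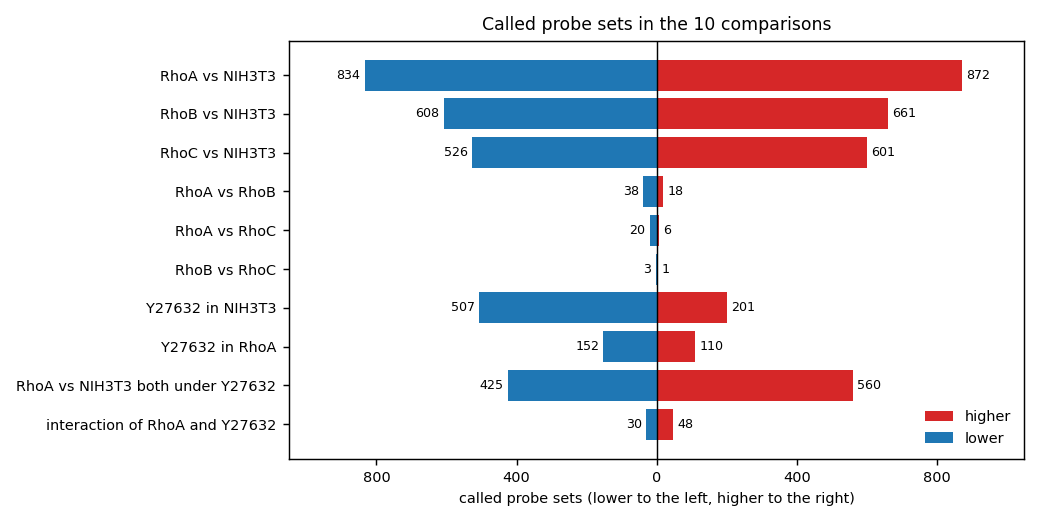
Number of probe sets called higher (right) and lower (left) in each of the 10 comparisons, out of 12422 tested. RhoA against NIH3T3 had 872 higher and 834 lower, and RhoB against RhoC 1 and 3.

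The changes of the 3 lines overlapped. Called in 1 direction in all 3 were 835 probe sets of 675 genes (457 higher, 378 lower), 2012 were called in any line, and 0 were called in all 3 in opposite directions. Msln, Cxcl1, Cxcl5 and Ccl2 rose and Ogn, Ptn, Smoc2, Nid2, Col6a2 and Timp3 fell in each. By the classes of the study's design text, 1185 probe sets were common to the 3 GTPases (655 higher, 530 lower), which is 67.3% of those classified, and 101, 61 and 50 were common to RhoA and RhoB, RhoA and RhoC, and RhoB and RhoC. Unique to 1 line were 233 in RhoA, 80 in RhoB and 50 in RhoC. Of the 233, 2 were called in the direct test of RhoA against both other lines and 12 against either, of the 80 for RhoB 0 and 4, and of the 50 for RhoC 0 and 1.

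The 3 comparisons share their NIH3T3 arrays. Across 7329 probe sets, which are not independent, the log2 changes correlated at 0.895 (RhoA and RhoB), 0.893 (RhoA and RhoC) and 0.932 (RhoB and RhoC), against 0.448, 0.448 and 0.430 in simulated unchanged lines, and at 0.845, 0.841 and 0.876 with the NIH3T3 arrays split between the comparisons. Their covariances were 0.349, 0.337 and 0.326, against 0.0147 in the simulation for RhoA and RhoB. RhoA and RhoB shared 577 rises and 471 falls, where independent lists of those sizes would share 46.4 and 40.8, simulated unchanged lines shared 0, and lists from split NIH3T3 arrays shared 195.5 and 213 (independent lists 11.9 and 12.6). For RhoA and RhoC the shared counts were 515 and 438 (independent 42.2 and 35.3), and for RhoB and RhoC 505 and 418 (independent 32.0 and 25.8). Splitting the NIH3T3 arrays does not remove a state of growth common to arrays on both sides of the split. The simulated unchanged lines hold no such state. How much of the overlap comes from such a state is therefore left open by both.

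Direct tests between the lines called few genes. RhoA and RhoB differed in 56 probe sets, 18 higher and 38 lower in RhoA (13 and 27 genes), and in 30 (without RhoA replicate 1 or 4) to 81 (without RhoA replicate 7) with single arrays left out. The count moved by over 1.5 times without any of RhoA replicates 1 to 4 (30 to 34) or RhoB replicates 2, 5 and 6 (36 to 37). Cd24a was higher in RhoA by 2.58 ± 0.14 (log2 ± SE, adjusted p = 8.3e-12) and Tnc by 1.91 ± 0.11 (adjusted p = 1.5e-11), as were Fhl1 (1.69 ± 0.33), Ccn2 (1.57 ± 0.33), Cdh11 (0.90 ± 0.15) and Col4a1 (0.74 ± 0.11). For Cd24a this difference, and that between RhoB and RhoC (-2.28), was smaller than its fall in RhoB against NIH3T3. Its mean log2 signal in RhoA and RhoC thus also lay below that in NIH3T3. Lower in RhoA were the proteoglycan gene Dcn (-1.83 ± 0.33), Ccl7 (-1.50 ± 0.27), Cxcl5 (-1.26 ± 0.26) and Gstm1 (-0.89 ± 0.15). Cxcl5 rose against NIH3T3 in both lines. The glutathione and oxidative stress list was lower, with 2 of 33 called down (6 adjusted over the list alone), a median of -0.20 and adjusted p = 7.6e-07 (adjusted p = 0.0289 with an estimated correlation). The count with scan day as a block was 91, of which 55 were shared, and the list median -0.22. On day 1 alone the count was 75, of which 24 were shared, and the list median -0.23. On day 3 alone the count was 3 and the list median -0.14, and without RhoA replicates 1 to 4, which were scanned on day 1, the count was 6 and the list median -0.09 (adjusted p = 0.0306). The day 3 scores of the list overlapped, at 0.063, 0.017 and -0.125 in RhoA and -0.047, -0.081 and 0.0004 in RhoB. Cd24a (2.53 ± 0.16) and Tnc (1.87 ± 0.13) kept their calls on day 3, where Fhl1 (1.44 ± 0.25), Ccn2 (0.91 ± 0.38), Cdh11 (0.69 ± 0.22), Col4a1 (0.83 ± 0.10), Dcn (-1.23 ± 0.36), Ccl7 (-0.80 ± 0.21), Cxcl5 (-0.72 ± 0.12) and Gstm1 (-0.27 ± 0.15) were not called. Ccn2 also lost its call with the block (1.54 ± 0.33, adjusted p = 0.0103).

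RhoA and RhoC differed in 26 probe sets, 6 higher and 20 lower in RhoA (4 and 16 genes), and in 3 (without RhoC replicate 5) to 83 (without RhoA replicate 6) with single arrays left out. Rhoc itself was lower in RhoA (-0.62 ± 0.10, adjusted p = 0.00391), and so were Ccl7 (-1.52 ± 0.27) and the metallothionein genes Mt2 (-1.04 ± 0.20) and Mt1 (-0.92 ± 0.18), while Tnc was higher (0.87 ± 0.11). With scan day as a block limma called 0 (2084 at an unadjusted p under 0.05), and on day 3 alone 0 (1956). The changes with the block and on day 3 were -0.50 ± 0.13 and -0.46 ± 0.12 for Rhoc, -1.17 ± 0.25 and -0.72 ± 0.21 for Ccl7, -1.17 ± 0.26 and -1.16 ± 0.21 for Mt2, -0.90 ± 0.24 and -0.80 ± 0.14 for Mt1, and 0.71 ± 0.11 and 0.67 ± 0.13 for Tnc, with adjusted p between 0.0120 and 0.193. RhoB and RhoC differed in 4 probe sets. Cd24a (-2.28 ± 0.15, adjusted p = 3.2e-10), Tnc (-1.04 ± 0.11, adjusted p = 1.06e-05) and Mgp, a gene of a matrix inhibitor of calcification (-1.22 ± 0.16, adjusted p = 0.000119), were lower in RhoB, and the kinase gene Pdk1 was higher (0.95 ± 0.10, adjusted p = 1.06e-05). With the block the count was 4, of which 3 were shared, and Mgp lost its call (-1.14 ± 0.19, adjusted p = 0.0106). On day 3 alone the count was 1, Cd24a, while Tnc (-1.20 ± 0.13, adjusted p = 0.0108), Mgp (-1.26 ± 0.27, adjusted p = 0.426) and Pdk1 (0.91 ± 0.18, adjusted p = 0.342) were not called. The glycolysis and hypoxia list was higher in RhoB than in RhoC, with 1 of 25 called (2 adjusted over the list alone), a median of 0.13 and adjusted p = 2.6e-05 (adjusted p = 0.000454 with an estimated correlation), and medians of 0.11 with the block and 0.16 on day 3. The genes named for the differences between lines, and those named for the comparison of treated cells, were chosen after their values were seen.

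The effect of Y27632 on NIH3T3 cells was measured against 8 untreated arrays of other scan days. Of 29 cytokine and chemokine genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), and the list did not pass (median 0.19, adjusted p = 0.0578). It passed with the untreated arrays of day 3 only (median -0.04, adjusted p = 0.036) and without NIH3T3 replicates 1 to 4 (median 0.14, adjusted p = 0.044). Cxcl5 rose by 3.79 ± 0.26 (log2 ± SE), from 105 ± 22.3 (SD, n = 8) to 1446 ± 267 (n = 5), Ccl2 by 3.63 ± 0.27, Cxcl1 by 2.93 ± 0.19 and Ccl7 by 2.72 ± 0.30. Saa3 (3.73 ± 0.62), Aqp1 (3.65 ± 0.58), the matrix protease gene Mmp9 (3.32 ± 0.32) and the ceruloplasmin gene Cp (3.13 ± 0.52) rose too. The largest falls were those of Ccn1 (-3.03 ± 0.29), the MAP kinase phosphatase gene Dusp6 (-2.78 ± 0.24), the actin-binding protein gene Tagln (-2.67 ± 0.29), the ephrin receptor gene Epha2 (-2.65 ± 0.30), Npr3 (-2.56 ± 0.28), the transcription factor gene Egr1 (-2.55 ± 0.54), Ptx3 (-2.54 ± 0.25) and the smooth muscle actin gene Acta2 (-2.48 ± 0.24), which went from 8162 ± 2188 to 1416 ± 181. Adjusted p ranged from 1.2e-09 for Cxcl1 to 0.00203 for Egr1. The call of Egr1 was lost without treated NIH3T3 replicate 3 (adjusted p = 0.0101) and with scan day as a random block.

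Of 23 SRF and MRTF target genes 8 fell in NIH3T3 with Y27632 and 1 rose (9 and 1 adjusted over the list alone), with Acta2, Tagln, Cnn2 (-1.17 ± 0.10) and Tpm1 (-0.77 ± 0.10) among those that fell. The median was -0.56 (adjusted p = 5.8e-08, and adjusted p = 0.0610 with an estimated correlation). Of 14 YAP and TEAD target genes 4 fell and 0 rose (5 and 1 adjusted over the list alone), including Ankrd1 (-2.01 ± 0.13), Amotl2 (-1.24 ± 0.09) and Lats2 (-1.12 ± 0.10), with a median of -0.27 (adjusted p = 0.00567, and adjusted p = 0.166 with an estimated correlation). Of 21 focal adhesion and integrin genes 5 fell (5 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.00219, and adjusted p = 0.0610 with an estimated correlation). Immediate-early genes fell in 8 of 25 cases (10 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.000283, and adjusted p = 0.343 with an estimated correlation). G2 and M phase genes rose in 10 of 31 cases (19 adjusted over the list alone), among them Pttg1 (1.61 ± 0.20) and Ccnb2 (1.44 ± 0.19), with a median of 0.90 (adjusted p = 1.0e-11, and adjusted p = 0.343 with an estimated correlation). Without NIH3T3 replicates 1 to 4 that median was 0.20. The cyclin D1 gene Ccnd1 (-1.27 ± 0.16), the matrix gene Sparc (-1.38 ± 0.15) and Sc5d of sterol synthesis (-1.42 ± 0.16) fell.

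Limma called 708 probe sets for Y27632 in NIH3T3, 201 higher and 507 lower (159 and 381 genes), which is 28.4% higher, against 44.6% after median centring. With scan day as a random block 361 were called, 359 of them shared, and without NIH3T3 replicates 1 to 4 591, 449 of them shared. With the untreated arrays of day 3 only the list medians were -0.38 for SRF and MRTF targets, -0.41 for YAP and TEAD targets, -0.29 for focal adhesion genes, -0.67 for immediate-early genes and 0.52 for G2 and M phase genes. The last leans on NIH3T3 replicate 3 (score -1.50). Replicates 5 and 6 of that day (0.14 and 0.04) lay above the treated mean of 0.01 ± 0.08 (SD, n = 5).

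With Y27632, Ccn1, Tagln and Acta2 fell in RhoA cells too. Their changes were -3.09 ± 0.30, -3.02 ± 0.30 and -2.86 ± 0.25 (log2 ± SE), and Acta2 went from 8883 ± 3304 (SD, n = 7) to 1150 ± 183 (n = 5). Fhl1 fell by 3.27 ± 0.37, as did Npnt, which encodes the integrin ligand nephronectin (-3.16 ± 0.42), and the myosin light chain gene Myl9 (-2.27 ± 0.18). Egr1 (-2.46 ± 0.56, adjusted p = 0.00720) and Ptgs2 (-2.26 ± 0.52, adjusted p = 0.00809) fell as well, though the call of Egr1 was lost on leaving out any of 11 single arrays (adjusted p up to 0.0234) and that of Ptgs2 on leaving out any of 12 (up to 0.0267). The largest rises were those of Car6 and Aqp1 (4.04 ± 0.50 and 3.52 ± 0.60), Cck (2.76 ± 0.55), Anxa8 (2.61 ± 0.38), Tmem176a (2.48 ± 0.36), the protease inhibitor gene Slpi (2.18 ± 0.42), Aldh1a1 (1.86 ± 0.35) and the glutathione transferase gene Gsta4 (1.79 ± 0.21). Other probe sets of Aqp1 and Aldh1a1 gave -0.51 and -0.14. Adjusted p ranged from 3.2e-08 for Myl9 to 0.00809 for Ptgs2. The call of Cck was lost without treated RhoA replicate 5 (adjusted p = 0.0104).

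Of 23 SRF and MRTF target genes 6 fell in RhoA cells with Y27632 (7 adjusted over the list alone), with a median of -0.40 (adjusted p = 1.7e-11, and adjusted p = 0.0107 with an estimated correlation). Of 14 YAP and TEAD target genes 6 fell (6 adjusted over the list alone), including Ankrd1 (-1.62 ± 0.14), Lats2 (-1.23 ± 0.11) and Amotl2 (-1.12 ± 0.09), with a median of -0.79 (adjusted p = 4.8e-09, and adjusted p = 0.00197 with an estimated correlation). Focal adhesion and integrin genes had 1 of 21 down (2 down and 1 up adjusted over the list alone), with a median of -0.37 (adjusted p = 0.00133, and adjusted p = 0.0208 with an estimated correlation). Immediate-early genes fell in 6 of 25 cases and rose in 1 (11 and 1 adjusted over the list alone), with Klf6 at -0.84 ± 0.09 and Jun at -0.97 ± 0.17. The median was -0.61 (adjusted p = 1.5e-06, and adjusted p = 0.271 with an estimated correlation). Collagens fell in 3 of 25 cases (4 adjusted over the list alone), including Col5a2 (-1.34 ± 0.15) and Col4a1 (-0.91 ± 0.11), with a median of -0.24 (adjusted p = 0.000743, and adjusted p = 0.0322 with an estimated correlation). Tnc, which was higher in the RhoA line, fell by 1.87 ± 0.12, from 2094 ± 291 to 576 ± 102. Glutathione and oxidative stress genes rose in 7 of 33 cases (8 adjusted over the list alone), among them Gsta4, Mt2 (1.41 ± 0.20), Mt1 (1.15 ± 0.20) and the epoxide hydrolase gene Ephx1 (1.00 ± 0.16). Their median was 0.43 (adjusted p = 1.5e-06, and adjusted p = 0.0155 with an estimated correlation). Cxcl1 fell by 0.95 ± 0.19.

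**Figure D3:**
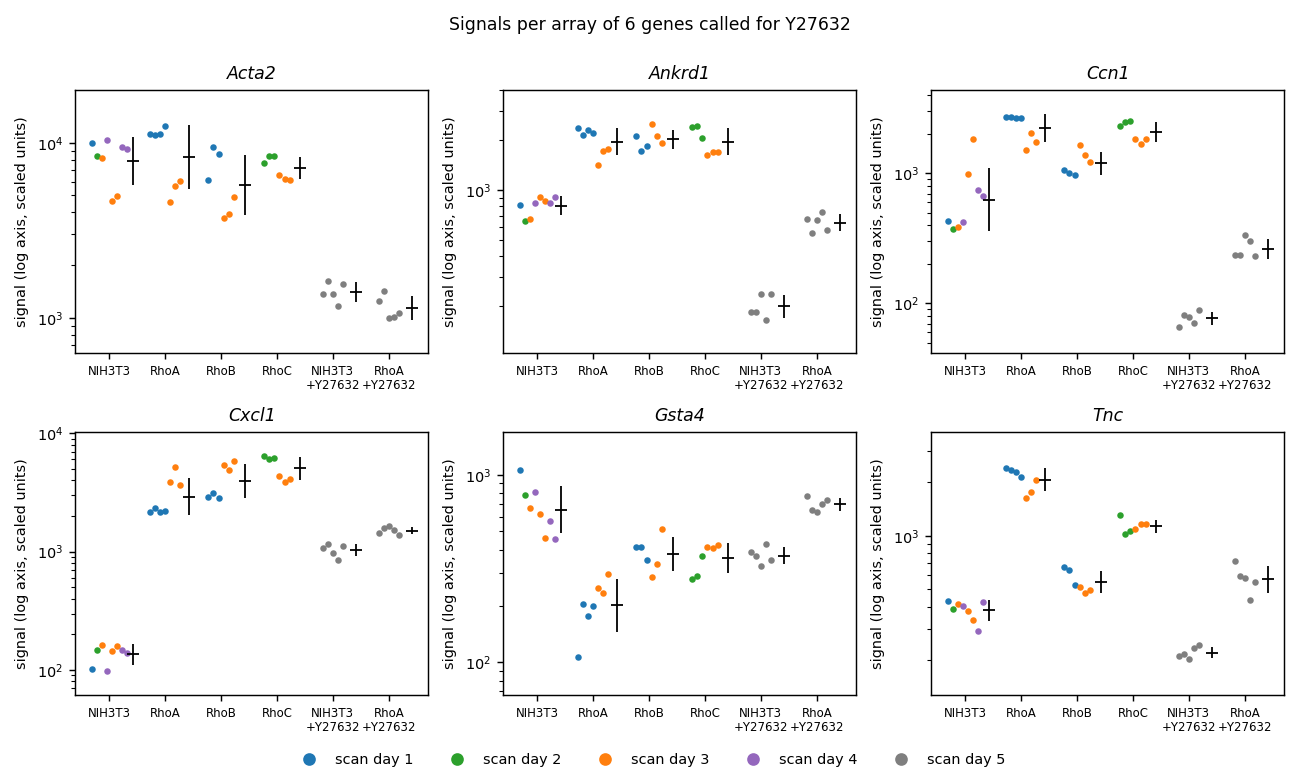
Signal per array (log axis, scaled units) of Acta2, Ankrd1, Ccn1, Cxcl1, Gsta4 and Tnc in the 6 groups, coloured by scan day, with the mean and SD of the log2 signals as a bar beside each group. Acta2 lay at 1416 ± 181 in treated and 8162 ± 2188 in untreated NIH3T3 cells (mean ± SD), and all treated arrays were scanned on day 5.

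Limma called 262 probe sets for Y27632 in RhoA cells, 110 higher and 152 lower (88 and 112 genes). With scan day as a random block 88 were called, all of them shared, and with the untreated arrays of day 3 only 60. Of the 29 called genes named for this comparison, the random block kept 19 calls, losing those of Cck, Slpi, Aldh1a1, Egr1, Ptgs2, Vcl, Jun, Ephx1, Mt1 and Cxcl1, all of them in the same direction. The untreated arrays of day 3 alone kept 18 of the 29, losing Car6 (4.04 over all arrays, 3.33), Cck (2.76, 1.64), Aldh1a1 (1.86, 1.27), Npnt (-3.16, -2.58), Egr1, Ptgs2, Vcl (-0.73, -0.53), Jun, Col4a1 (-0.91, -0.73), Ephx1 (1.00, 0.75) and Mt1 (1.15, 0.85), while Slpi (0.78) and Cxcl1 (-1.47) kept theirs. Without RhoA replicates 1 to 4 the changes were the same and 16 calls were kept, with Car6 and Col4a1 among them. Aqp1 (3.52, 2.39), Tmem176a (2.48, 1.79), Slpi and Mt2 then lost theirs. With the untreated arrays of day 3 only the list medians were -0.34 for SRF and MRTF targets, -0.70 for YAP and TEAD targets, -0.26 for focal adhesion genes, -0.78 for immediate-early genes, -0.20 for collagens and 0.21 for glutathione and oxidative stress genes. The effects of Y27632 in NIH3T3 and in RhoA cells, which share no array, were called in both as 24 rises and 69 falls (independent lists 1.78 and 6.20) and in opposite directions for 6 probe sets, with a correlation of 0.445 across probe sets. Both effects set day 5 against other days, so an effect of day 5 would also give shared calls and a correlation.

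**Figure D4:**
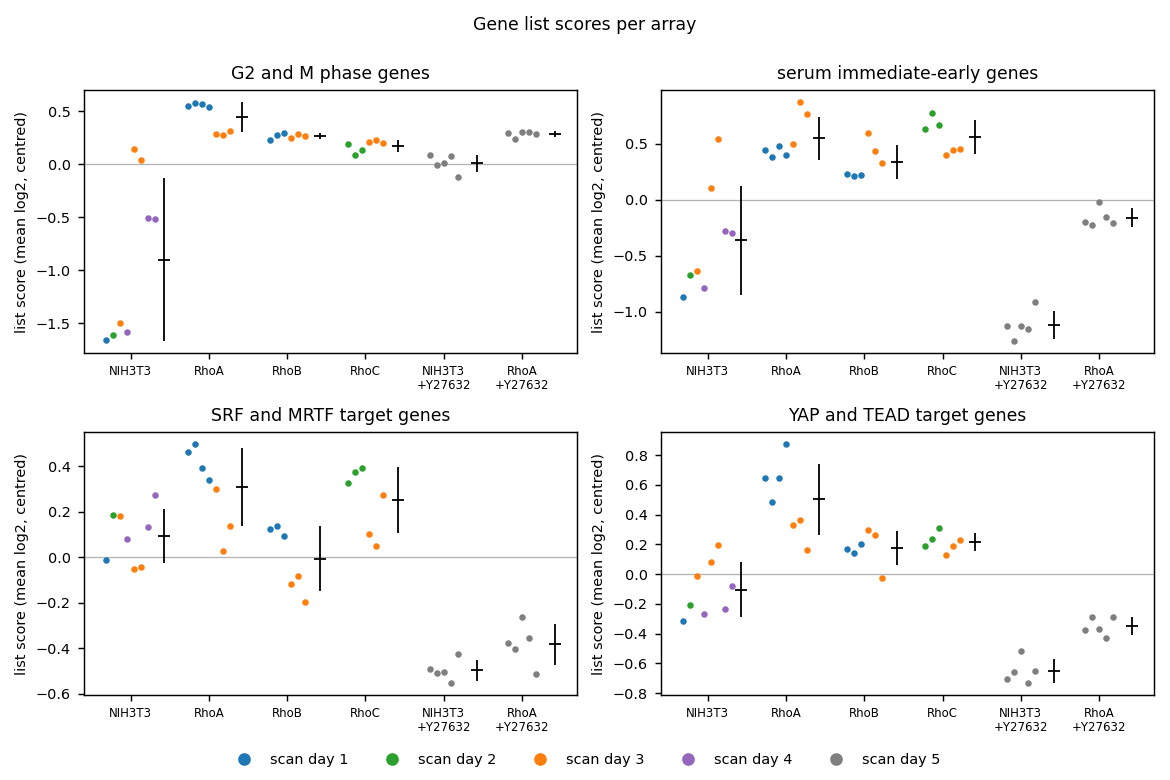
List score per array (mean log2 signal over the list's genes, centred on all arrays) of 4 gene lists in the 6 groups, coloured by scan day, with mean and SD as a bar beside each group. SRF and MRTF targets lay at 0.31 ± 0.17 in RhoA and -0.38 ± 0.09 in treated RhoA cells, and G2 and M phase genes at -0.90 ± 0.77 in NIH3T3.

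Treated RhoA cells were compared with treated NIH3T3 cells, all scanned on 1 day, to see how much of the RhoA difference is present under the inhibitor. Postn, which encodes periostin, was lower (-5.30 ± 0.33, log2 ± SE, n = 5 and 5), as were Col6a2 (-1.96 ± 0.14), Col6a3 (-1.95 ± 0.13), Col3a1 (-1.66 ± 0.12) and Mmp9 (-2.79 ± 0.36). Epha2 (3.49 ± 0.33), Plaur (3.17 ± 0.31), Dusp6 (2.91 ± 0.27), Fosl1 (2.37 ± 0.27), Dusp1 (2.10 ± 0.18), Ccnd1 (1.96 ± 0.18), Ccn1 (1.78 ± 0.32), Ankrd1 (1.67 ± 0.15) and Tnc (1.37 ± 0.13) were higher. Collagens had 10 of 25 down and 1 up (11 and 1 adjusted over the list alone, median -0.59, adjusted p = 2.0e-08, and adjusted p = 0.00220 with an estimated correlation). Other matrix genes had 13 of 33 down and 1 up (14 and 1 adjusted over the list alone, median -0.64, adjusted p = 2.0e-06, and adjusted p = 0.0182 with an estimated correlation). Myc targets had 16 of 33 up (16 adjusted over the list alone, median 0.55, adjusted p = 8.8e-11, and adjusted p = 0.0911 with an estimated correlation) and immediate-early genes 9 of 25 (9 adjusted over the list alone, median 0.58, adjusted p = 1.2e-06, and adjusted p = 0.229 with an estimated correlation). Limma called 985 probe sets, 560 higher and 425 lower (430 and 354 genes). The 2 groups were of different chip lots, and with chip lot as a random block 601 were called, all of them among the 985.

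The RhoA effect under Y27632 followed the effect without it at a slope of 0.649 (bootstrap SD 0.0474, 95% interval 0.556 to 0.743, 1000 draws) over the 1706 called probe sets. The slope was 0.661 for those higher and 0.638 for those lower in RhoA, 0.680 with the probe sets selected on other arrays, and 0.750 without NIH3T3 replicates 1 to 4. The value of 0.750 lies above the interval. The bootstrap keeps the selected probe sets fixed and draws the arrays of a group as if they were alike. The interval therefore does not cover the difference among the NIH3T3 arrays. Of the 1706, 1613 (94.6%) had the same sign under the inhibitor, 669 were called in the same direction and 4 in the opposite one. Y27632 in RhoA cells moved 118 of them back (61 that were higher in RhoA, among them Tnc, Fhl1 and Ptgs2, and 57 that were lower, among them Aldh1a1) and 19 further. The counts moved back and further share the untreated RhoA arrays with the selection; with these arrays split, 7 of 7 and 8 of 8 called probe sets moved back.

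**Figure D5:**
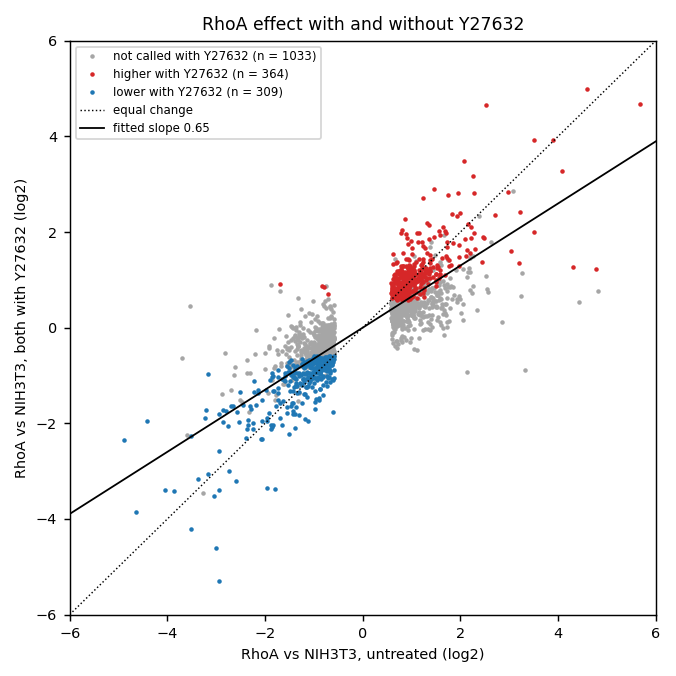
RhoA minus NIH3T3 difference (log2) of the 1706 called probe sets with Y27632 in both cell types (vertical axis) against without it (horizontal axis), coloured by the call with Y27632, with the line of equal change (dotted) and the fitted slope of 0.649 (solid). Of these, 1613 had the same sign on both axes.

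The interaction tests whether Y27632 acted differently on RhoA and NIH3T3 cells. Cxcl1, Cxcl5 and Ccl2, which rose with Y27632 in NIH3T3 cells, had interactions of -3.88 ± 0.27 (log2 ± SE, adjusted p = 7.6e-09), -3.54 ± 0.37 (adjusted p = 8.4e-06) and -3.04 ± 0.39, and their changes in RhoA cells were -0.95, 0.25 and 0.59. All of them were already higher in untreated RhoA than in untreated NIH3T3 cells. The interaction was also negative for Mmp9 (-3.37 ± 0.46), Postn (-2.36 ± 0.42), Jun (-1.39 ± 0.24) and Tnc (-1.08 ± 0.17). The shared sign does not mean a rise in NIH3T3 cells, and Jun and Tnc fell with Y27632 in RhoA cells. Positive interactions were found for Aldh1a1 (3.97 ± 0.49), Gsta4 (2.61 ± 0.29), Ogn (2.46 ± 0.31), Timp3 (2.21 ± 0.23), the amino acid transporter gene Slc1a5 (1.43 ± 0.17), the interferon-inducible gene Ifi202b (1.42 ± 0.17) and Serpinb6a (1.09 ± 0.13). Cytokine and chemokine genes had 4 of 29 called (5 adjusted over the list alone), with a median of -0.54 (adjusted p = 7.7e-05, and adjusted p = 0.0736 with an estimated correlation), and -0.37 with scan day as a block. Glutathione and oxidative stress genes had 3 of 33 up (6 up and 1 down adjusted over the list alone), with a median of 0.66 (adjusted p = 7.7e-05, and adjusted p = 0.0795 with an estimated correlation), and 0.50 with the block, and 0.35 without RhoA replicates 1 to 4. G2 and M phase genes had 0 of 31 called by limma (9 down adjusted over the list alone), with a median of -1.08 (adjusted p = 8.8e-17, and adjusted p = 0.409 with an estimated correlation), which was -0.35 without NIH3T3 replicates 1 to 4. Limma called 78 probe sets, 48 higher and 30 lower (39 and 20 genes), 48 (without treated RhoA replicate 1 or 4) to 107 (without NIH3T3 replicate 6) with single arrays left out, 47 with scan day as a block (38 shared), and 46 without NIH3T3 replicates 1 to 4. It called 39 without RhoA replicates 1 to 4 (18 higher, 25 shared), 26 with chip lot as a random block, and 9 with the untreated arrays of day 3 only (1 higher, 5 shared), where Cxcl1 (-4.20), Cxcl5 (-4.04), Ccl2 (-3.89) and Gsta4 (2.06) kept their calls and the other genes named here did not, all of them in the same direction.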

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

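The tests of the 3 patterns below and the counts over other splits of the arrays were chosen after the results were seen.

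Single arrays stood far from the others of their group in 8 of 284 pairs of named gene and group (2.82%), where chance marks about 1 in 20, and no array was marked more than 1 time. The measure is the gap to the nearest other array divided by the group's range. Odc1 was low in NIH3T3 replicate 3 (0.55; signal 342 against 417 to 490), Vasp in treated NIH3T3 replicate 1 (0.916; 1331 against 1653 to 1686), Agtr2 in RhoA replicate 4 (0.713; 26.97 against 75.9 to 115) and Myl9 in RhoA replicate 7 (0.646; 177 against 272 to 344). Fhl1 was low in treated RhoA replicate 1 (0.755; 196 against 253 to 275) and Cd24a in RhoB replicate 2 (0.72; 229 against 384 to 469). Car6 was high in RhoA replicate 5 (0.771; 116 against 9.90 to 17.4) and Ptgs2 in RhoA replicate 6 (0.638; 4172 against 2925 to 3326).

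Differences between groups were marked where a direct test called them. These were the 56 probe sets between RhoA and RhoB, 26 between RhoA and RhoC, 4 between RhoB and RhoC and 78 for the interaction. The 10 genes of lowest adjusted p for the interaction were Cxcl1 (-3.88), Timp3 (2.21), Cxcl5 (-3.54), Gsta4 (2.61), Slc1a5 (1.43), Serpinb6a (1.09), Ifi202b (1.42), Aldh1a1 (3.97), Ogn (2.46) and Ccl2 (-3.04). Of the 66 control probe sets, which no comparison used, limma called 4 between RhoA and NIH3T3, 4 for RhoB, 4 for RhoC and 3 between treated RhoA and treated NIH3T3 cells, most of them made for the transferrin receptor, a mouse transcript.

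Mitotic genes lay lower in NIH3T3 than in the Rho lines. Scan day is argued against as the cause, since the median for RhoA was 1.41 with scan day as a block, and replicates 3, 5 and 6 of NIH3T3, of 1 day and 1 chip lot, had scores of -1.50, 0.14 and 0.04. The spread of the scores over NIH3T3 arrays was 5.4 times the largest spread within a Rho line. That ratio restates the difference seen among the NIH3T3 arrays. The low scores were those of replicates 1 to 4, scanned on days 1, 2, 3 and 4 with chip lots 1, 2, 4 and 3. Replicates 4, 7 and 8, also of 1 day and 1 chip lot, had scores of -1.58, -0.50 and -0.51. The split among the NIH3T3 arrays thus followed neither scan day nor chip lot. The ratio is no separate test of whether these cultures were in different states of growth, which is left open. An effect of the GTPases stays open, as 1 NIH3T3 array lay within the range of the Rho line arrays and the RhoA median was 0.63 without NIH3T3 replicates 1 to 4.

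The chemokine genes Cxcl1, Cxcl5, Ccl2 and Ccl7 and the serum amyloid gene Saa3 rose with Y27632 in NIH3T3 and were not called higher in RhoA cells (Cxcl1 2.93 and -0.95, Cxcl5 3.79 and 0.25, Ccl2 3.63 and 0.59, Ccl7 2.72 and 0.86, Saa3 3.73 and -0.49), and the difference passed its own test for Cxcl1, Cxcl5 and Ccl2, not for Ccl7 (adjusted p = 0.0212) or Saa3 (adjusted p = 0.0123). One shift of scan day 5 in all its arrays would cancel in that test, so that it is argued against for Cxcl1, Cxcl5 and Ccl2 (highest adjusted p of the 3 7.8e-05), which also kept their calls with the untreated arrays of day 3 only. For Ccl7 and Saa3 it is left open (lowest adjusted p of the pair 0.0123). RhoA cells among the treated NIH3T3 cells are argued against too: the 5 genes would need a share of 41.2%, while 8 other genes, at least 4-fold higher in RhoA and in treated RhoA cells than in untreated NIH3T3, gave a median share of 5.35%, an upper quartile of 13.8% and, for Msln, 1.64%, with 0 of the 8 at or above the share needed. An effect of Y27632 and a culture difference of the treated NIH3T3 arrays cannot be told apart, because treated and untreated NIH3T3 arrays share 0 scan days. Without Y27632, RhoA cells already held Cxcl1, Cxcl5 and Ccl2 above NIH3T3 cells, by 4.4, 4.8 and 4.3 in log2. The cell types thus started from different levels, and whether this limited the change in RhoA cells was not tested.

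RhoA and RhoB differed in 56 probe sets, and in 3 on scan day 3 alone. With scan day as a block 55 of the 56 kept their calls, at a median of 0.988 times the difference without it. This is no test of a day 1 shift shared by both lines. Such a shift nearly cancels between them, as days 1 and 3 held 4 and 3 RhoA and 3 and 3 RhoB arrays. Signed as the difference, RhoA changed from day 3 to day 1 by a median of 0.337 over the 56, and RhoB by 0.062 (quartiles -0.171 and 0.243). The block does not remove a change of RhoA alone. The 411 probe sets picked on day 1 differed there by a median of 0.82 (0.823) and on day 3 by 0.24 (0.2444), with quartiles of 0.00365 and 0.467 and 75.7% in the same direction. The day 3 value lies between a difference on day 1 alone and an equal one on both days. Picking on day 1 also raises the day 1 median by itself, so that these cannot be told apart.

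Each comparison was set against 100 splits of its arrays, the real one included. For the counts of called probe sets, and for the count common to the 3 GTPases, only the real split, 1 of 100, was as large. This argues against a chance assignment of arrays to groups, though for RhoB against RhoC another split gave 3 to the real 4. The real and the highest other counts were 1706 and 936 (RhoA), 1269 and 634 (RhoB), 1127 and 561 (RhoC), 56 and 0 (RhoA against RhoB), 26 and 0 (RhoA against RhoC), 4 and 3 (RhoB against RhoC), 708 and 24 (Y27632 in NIH3T3), 262 and 3 (Y27632 in RhoA), 985 and 1 (treated RhoA against treated NIH3T3), 78 and 0 (interaction) and 1185 and 4 (common). These splits take no account of batches: for RhoA against RhoC limma called 0 with scan day as a block (2084 at an unadjusted p under 0.05) and 0 with chip lot as a block (1409). A split by scan day, days 1 and 2 against day 3, was counted apart from these. For RhoA with RhoB it called 162, more than the 56 between the lines, where the count with scan day as a block was 91 and on day 3 alone 3. It called 10 for RhoA with RhoC and 0 for RhoB with RhoC.

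For the number of shifted gene lists, fewer than 5 of 100 splits were as large for RhoA (13 lists, 4 of 100 splits as large, highest other 15), RhoB (13, 3 of 100, 16), RhoA against RhoB (12, 1 of 100, 10), RhoA against RhoC (7, 2 of 100, 7), RhoB against RhoC (12, 1 of 100, 11), Y27632 in NIH3T3 (10, 3 of 100, 11) and Y27632 in RhoA (9, 4 of 100, 9). At least 5 were for RhoC (11, 6 of 100, 12), treated RhoA against treated NIH3T3 (10, 5 of 100, 11) and the interaction (5, 27 of 100, 10), where chance cannot be excluded. The limit of 5 was set after the results were seen. For RhoA, RhoB and Y27632 in NIH3T3 another split shifted more lists than the real one, so chance is not excluded there either. The other splits shifted a median of 5 lists for RhoA, 5 for RhoB, 6 for RhoC and 1 to 3 for the other comparisons. They take no account of batches here either: with scan day as a block RhoA against RhoC gave 3 lists. With a correlation estimated from each list camera gave 0 for RhoA (11 at an unadjusted p under 0.05), 0 for RhoA against RhoC (4), 0 for Y27632 in NIH3T3 (8), 1 for RhoA against RhoB (5) and 1 for RhoB against RhoC (3). Without RhoB replicate 6 the count for RhoB against RhoC was 6.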

How the results depend on the processing

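The alternatives that leave out sets of arrays or use single scan days were chosen after seeing the data; the others were planned. Over all alternatives 538 counts stayed within 1.5 times their value and 119 did not. Of the values for named genes 3781 kept their direction and side of the threshold, 164 lost a call, 6 gained one and 20 reversed. Of those for gene lists 1249 kept both, 108 lost a call and 3 reversed. Where a construction does not show why a value moved, the cause was not tested. RhoA, RhoB and RhoC stand below for the comparison of each line with NIH3T3.

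Without a fold minimum limma called 2657 (RhoA, 1706 with it), 1978 (RhoB, 1269) and 1757 (RhoC, 1127). With a fold of at least 2 it called 715, 516 and 467, 19 between RhoA and RhoB (56), 8 between RhoA and RhoC (26), 230 and 92 for Y27632 in NIH3T3 (708) and RhoA (262) and 441 between the treated groups (985). Unadjusted p gave 213, 229 and 54 between RhoA and RhoB, RhoA and RhoC, and RhoB and RhoC (4), 532 for Y27632 in RhoA and 545 for the interaction (78). The F-statistic of the design text gave 170, 198, 53, 467 and 533 there without adjustment. With adjustment it gave 33 between RhoA and RhoB, 7 between RhoB and RhoC and 439 for Y27632 in NIH3T3. These settings add or remove probe sets by construction.

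Median centring gave 6 between RhoA and RhoC and 46 for the interaction, and turned Rock1 in RhoB to 0.0249. It moved the share of higher calls in RhoB from 52.1% to 66.7%, for Y27632 in NIH3T3 from 28.4% to 44.6% and between RhoA and RhoB from 32.1% to 20.4%. Neither scaling moved the median of all probe sets by over 0.1. Quantile normalization gave 7 list shifts between RhoB and RhoC (12 without it). An offset of 16 gave 50 between RhoA and RhoC. Trend and robust moderation gave 88 there and 136 for the interaction. All 37 arrays in 1 fit gave 98 between RhoA and RhoB, 98 between RhoA and RhoC and 162 for the interaction, and array weights gave 187, 242, 172 and, for Y27632 in RhoA, 519.

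The replicate numbers do not pair the arrays. Of 62 pairs with the same number in different groups 12 correlated above 0.1 (median -0.0238), and in 13 of the 62 the array of the first group correlated best with its own number in the other, a hint from the data and not from the design. With a replicate block limma called 32 between RhoA and RhoB, 4 between RhoA and RhoC and 40 for the interaction.

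Scan day as a block gave 91 between RhoA and RhoB, 0 between RhoA and RhoC (2084 at an unadjusted p under 0.05) and 47 for the interaction, with 3 list shifts between RhoA and RhoC (7 without the block), and Rock1 in RhoB (0.0354) and Rhoa in RhoC (-0.0127) reversed. As a random block, scan day gave 361 for Y27632 in NIH3T3 and 88 in RhoA. Chip lot as a block left 0 between RhoA and RhoC (1409 at an unadjusted p under 0.05). Chip lot as a random block gave 355 and 131 for Y27632 in NIH3T3 and RhoA, 601 between the treated groups and 26 for the interaction, and fluidics module as a block 49 for the interaction. Scan day and lot could not be fitted as fixed blocks for the effect of Y27632, since treated and untreated arrays share none.

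With a correlation estimated from each list, camera shifted 0 lists for RhoA (13 otherwise) and 6 for RhoC (11), 1, 0 and 1 between RhoA and RhoB (12), RhoA and RhoC (7), and RhoB and RhoC (12), 0 and 5 for Y27632 in NIH3T3 (10) and RhoA (9), 4 between the treated groups (10) and 0 for the interaction (5). Where it gave 0, the lists at an unadjusted p under 0.05 numbered 11 (RhoA), 4 (RhoA against RhoC), 8 (Y27632 in NIH3T3) and 3 (interaction). Fry, which tests each list against no change where camera compares it with the other genes, gave 24 (RhoA), 20 (RhoB), 19 (RhoC), 4 (RhoA against RhoC), 7 (RhoB against RhoC), 16 (Y27632 in NIH3T3) and 16 (treated groups). Other probe sets of a gene reversed Ereg (-0.0169) and Aldh1a1 (0.18) in RhoA, Rhoc (-0.0230), Rock1 (0.12) and Cd44 (-0.14) in RhoB, and Rhoa (-0.0102) and Aqp1 (-0.48) in RhoC. For Y27632 they reversed Rhoa in NIH3T3 (0.46), and Aqp1 (-0.51) and Aldh1a1 (-0.14) in RhoA cells.

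Without NIH3T3 replicates 1 to 4 limma called 812 for RhoB and 46 for the interaction, the slope was 0.750, and the G1 and S phase list under Y27632 in NIH3T3 turned to -0.0909. Without RhoA replicates 1 to 4 it called 6 between RhoA and RhoB (7 lists), 0 between RhoA and RhoC (2 lists), 73 for Y27632 in RhoA and 39 for the interaction (3 lists), and the Myc list under Y27632 in RhoA turned to 0.00606. Day 3 alone gave 347, 428 and 323 for RhoA, RhoB and RhoC, 636 common to the 3, 3 between RhoA and RhoB (7 lists), 0 between RhoA and RhoC (1956 at an unadjusted p under 0.05; 1 list) and 1 between RhoB and RhoC (6 lists). Rhoc in RhoA (0.0123), Rock1 in RhoB (0.14) and Rhoa in RhoC (-0.0868) reversed there. Day 1 alone gave 498 for RhoB, with Rhoa in RhoA (0.0166) and Rhoc in RhoB (-0.29) reversed, and day 2 alone 0 for RhoC (2297 at an unadjusted p under 0.05), with Rhoc at -0.0540. With the untreated arrays of day 3 only, Y27632 called 304 in NIH3T3 and 60 in RhoA, the interaction 9 (3 lists), and the Myc list in RhoA was 0.00606. These sets hold fewer arrays, which lowers counts by itself. Day 1 and day 2 each held 1 NIH3T3 array, which gives no spread for that group. The counts against NIH3T3 on these days, the 0 for RhoC included, therefore decide nothing.

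Leaving out each array in turn gave 1613 to 1809 (RhoA), 1160 to 1367 (RhoB), 1040 to 1226 (RhoC), 30 to 81 (RhoA against RhoB), 3 to 83 (RhoA against RhoC), 4 to 5 (RhoB against RhoC), 525 to 760 and 183 to 303 (Y27632 in NIH3T3 and RhoA), 865 to 945 (treated groups), 48 to 107 (interaction), 1103 to 1269 (common) and a slope of 0.617 to 0.670. Shifted lists numbered 12 to 14, 12 to 13 and 10 to 12 in RhoA, RhoB and RhoC, 9 to 13, 5 to 7 and 6 to 12 between the lines, 7 to 12 and 8 to 9 for Y27632, 9 to 10 between the treated groups and 5 to 6 for the interaction. Counts between RhoA and RhoB moved by over 1.5 times without RhoA 1, 2, 3 or 4 (30, 34, 32, 30) or RhoB 2, 5 or 6 (36, 37, 37). Those between RhoA and RhoC did without RhoA 1 to 7 (5, 5, 5, 10, 76, 83, 75) or RhoC 1 to 6 (4, 15, 8, 5, 3, 7). The interaction count did without treated NIH3T3 1 (51) or treated RhoA 1, 2 or 4 (48, 50, 48), and the lists between RhoB and RhoC did without RhoB 6 (6).

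Among named genes, Rhob in RhoB, Egr1, Vasp and Cdk1 for Y27632 in NIH3T3, and Cck, Cxcl1, Egr1, Ptgs2 and Vcl for Y27632 in RhoA lost calls with single arrays left out. Cdk1 did so without treated NIH3T3 replicate 1 (0.92) or 4 (0.91), Vasp without treated NIH3T3 replicate 1 (-0.58) and Cxcl1 without treated RhoA replicate 5 (-0.92). Vcl lost its call without RhoA replicates 1 to 4 or any treated RhoA array, left out 1 at a time (-0.68 to -0.76). Rhoa in RhoC, not called, ranged from -0.00743, without NIH3T3 replicate 1, to 0.0739, without NIH3T3 replicate 3. Of the lists called, 12 of 13 (RhoA), 11 of 13 (RhoB), 10 of 11 (RhoC), 7 of 10 and 7 of 9 (Y27632 in NIH3T3 and RhoA) kept their calls in every such fit. The number of arrays limits the precision: between 55.9% and 61.8% of probe sets per array reached a signal of 100, changes below it are not called, and minimums of 0 or 200 moved no count by over 1.5 times. The replicates are cultures of 1 pool per line, and every effect of Y27632 shares its contrast with scan day 5.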

Other observations

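Chaperone genes were also higher in RhoA and RhoC, and glycolysis genes in RhoA. Of 19 heat shock and chaperone genes 6 rose and 1 fell in RhoA (6 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.00758, and adjusted p = 0.0709 with an estimated correlation). In RhoC 6 rose (6 adjusted over the list alone, median 0.24, adjusted p = 0.00242, and adjusted p = 0.0352 with an estimated correlation). The list was also higher in treated RhoA than in treated NIH3T3 cells, with 6 up (6 adjusted over the list alone, median 0.37, adjusted p = 0.000114, and adjusted p = 0.0128 with an estimated correlation). Glycolysis and hypoxia genes had 7 of 25 up and 2 down in RhoA (7 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0133, and adjusted p = 0.0709 with an estimated correlation). In RhoC that list did not pass (median 0.24, adjusted p = 0.09995).

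No list of another cell type passed in RhoA against NIH3T3: epithelial markers had a median of 0.06 (adjusted p = 0.786), endothelial markers -0.07 (0.938), macrophage and leukocyte markers -0.05 (0.944) and neural and glial markers -0.02 (0.781). The genes of the Rho family GTPases had 2 of 13 down (2 adjusted over the list alone) and a median of -0.33 (adjusted p = 0.0681). Interferon-induced genes had 1 of 28 up and 2 down (1 and 2 adjusted over the list alone) and a median of 0.02 (adjusted p = 0.858).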
